A study of Mus musculus with 9 samples.

How the data were processed

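The data are RNA sequencing libraries of mouse nasal mucosa in 3 groups (control, papain, and papain with mesenchymal stromal cell exosomes), 3 libraries each, and groups and replicate numbers were taken from the sample titles. The authors deposited a single table of FPKM values for 21930 Ensembl gene identifiers. Reads were trimmed with fastp 0.19.4, aligned with HISAT2 and quantified with StringTie against mm10, per the submitters' processing notes. The annotation, the strand setting, the versions of the aligner and quantifier, and the treatment of reads shared between paralogs are not given in the sources used here. FPKM divides by all fragments of a library, so a change in a few abundant genes moves every other value. Symbols were found for 21817 of the identifiers, 113 had none, and 26 symbols belonged to more than 1 identifier. Lengths and coordinates came from GENCODE M21 (GRCm38), which held 21888 of the identifiers.

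Depth was estimated from 4394 single-transcript genes, taking as the value of 1 fragment the peak in the density of FPKM times exon length (in kilobases) between 0.03 and 0.08. This gave about 15.1 to 24.7 M fragments per library (M, mega). The window was set by hand and can only return 12.5 to 33.3 M, so these depths are rough. Only 15.9% to 21.6% of low values lay within 5% of a whole multiple of that value, against 9.09% for evenly spread values, so whole reads could not be recovered and no count test was run. An FPKM of 0 is described as listed at 0. Spearman correlations between libraries were 0.979 to 0.988 within groups and 0.966 to 0.98 between groups, so that no library was a copy of another. Y-linked genes were present in every library.

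Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, all 9 libraries in a single fit (6 residual degrees of freedom), genes of FPKM at least 1 in at least 3 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists with at least 3 tested members, and again with an estimated correlation and with fry. The lists were 30 in number, and those of T cell markers and of Th2 and ILC2 markers had too few tested members. A call of a list is relative to the other genes tested. Some lists share members, such as Alox15 (IL-13-response and eicosanoid) and Hpgds and Alox5ap (tuft and eicosanoid), so their calls are not independent. Genes were named by a rule set before the data were examined: the 6 largest rises and 6 largest falls among called genes whose libraries did not overlap, with a mean of at least 2 FPKM in the higher group and no Gm or Rik name, the up to 2 called members of smallest p in each list, and 16 genes of type 2 inflammation and remodelling in every comparison. Not every gene so named is described, and the choice among them was made after their values were seen. All of them that were tested enter the alternatives.

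Because the libraries differed in scale, every comparison was repeated after dividing each library by the median of its ratios to the geometric mean over genes above 0 in all libraries, which left 12507 tested genes. The alternatives set before the data were examined were a pseudocount of 0.1, no filter and a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, rescaling to a common sum (TPM), fits of the 2 groups compared only, a replicate block, array weights, no mean-variance trend, each library left out, and thresholds of 0.05 on the adjusted or unadjusted p with a log2 change of at least 1, camera with an estimated correlation, fry, and selection and measurement in different papain libraries. The array-weight fit stopped before its tolerance was reached. Combinations of median-of-ratios scaling with other alternatives were chosen after seeing the data. A correlation of deviations from group means gave no sign that numbers shared by the titles pair the libraries. So few libraries per group cannot exclude it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with NumPy 2.4.6 and pandas 2.3.3.

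On simulated data with the real means and spreads and independent noise per gene, limma recovered 93, 87 and 90 of 100 genes changed 2-fold among 12738 genes (papain against control, exosomes against papain, exosomes against control) and 100 of 100 changed 4-fold in each, with 10, 15 and 12 unchanged genes called. Camera and fry called the raised list and 0 of 20 unchanged lists in each. These lists were random genes with independent noise. The check therefore cannot show how often unchanged lists of correlated genes would be called. To judge the share of papain genes moving back, exosome libraries without an effect were simulated 100 times around the control and papain libraries, with papain effects shrunk by a normal prior and noise drawn from the residuals of all libraries. That prior draws simulated libraries toward control, which by construction moves genes back, and the simulation was not tested on data with a known answer.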

Results

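Mouse nasal mucosa was profiled by poly(A) RNA sequencing in 9 libraries, 3 in each of 3 groups. Papain, a plant cysteine protease, was given into the nose at 20 µg in 20 µl on days 0 to 2 and 7 to 11 to produce a model of eosinophilic chronic rhinosinusitis. The papain+MSC-Exos group also received exosomes, the small vesicles shed by mesenchymal stromal cells, on days 7 to 11, and tissue was taken on day 12. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these libraries, which may be technical. Values are FPKM (fragments per kilobase of transcript, relative to all fragments of the library) as the authors deposited them, and fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A rough estimate from low values puts the depth at about 15.1 to 24.7 M fragments per library (M, mega). Coordinates are those of GENCODE M21 on GRCm38.

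A small set of secretory genes took a large and varying share of the libraries. The 15 genes of highest mean FPKM, which include the odorant-binding lipocalins Obp1a, Obp1b, Obp2a and Obp2b, the major urinary proteins Mup4 and Mup5, and Bpifb9a and Bpifb9b, took 51.5% ± 1.55 (SD, n = 3) of the length-weighted FPKM in controls. Their share was 41.2% ± 9.08 after papain and 23.2% ± 9.72 with exosomes (n = 3 each). Papain library 2 (51.4%) lay with the controls, and exosome library 3 (34.2%) lay with the other papain libraries. Where these genes took less of a library, the rest of the table took more. The median log2 change of the tested genes was 0.19 for papain against control, 0.56 for exosomes against papain and 0.76 for exosomes against control. Each comparison is therefore also given after median-of-ratios scaling, called the scaled values, in which these medians were -0.00399, -0.00587 and 0.00915.

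**Figure D1:**
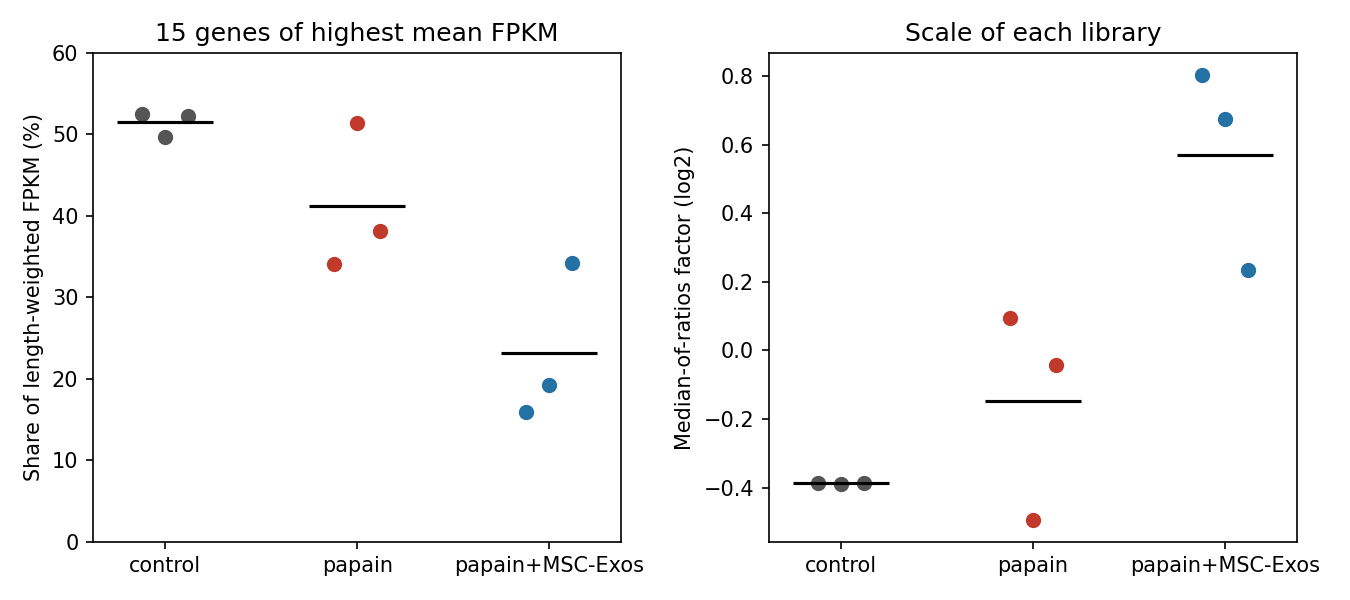
Left, the percent of length-weighted FPKM taken by the 15 genes of highest mean FPKM in each library; right, the log2 median-of-ratios factor of each library. Points are libraries and bars are means of 3; the share was 49.7% to 52.5% in controls and 16.0% to 34.2% with exosomes.

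The comparison of papain with control asks which transcripts change in the model itself. Chil4 (Ym2), a chitinase-like protein of type 2 inflammation (chromosome 3, 106201490 to 106219507), rose from 6.62 ± 4.63 to 7075 ± 1317 FPKM (mean ± SD, n = 3), a log2 change of 10.09 ± 0.35 (SE, adjusted p = 9.51e-14). The eosinophil-attracting chemokines rose with it, Ccl11 from 0.633 ± 0.137 to 3.97 ± 0.229 FPKM (adjusted p = 2.46e-06) and Ccl24 from 0.0275 ± 0.0283 to 3.19 ± 0.614 FPKM (adjusted p = 5.84e-08). Retnla, a marker of alternatively activated macrophages, rose from 0.413 ± 0.53 to 20.1 ± 9.75 FPKM (adjusted p = 5.84e-08). The largest falls were in odorant receptor genes, led by Olfr727 (chromosome 14, 50123186 to 50128746), which fell from 10.2 ± 1.38 to 0.931 ± 0.92 FPKM (log2 change -2.62 ± 0.26, adjusted p = 1.99e-06).

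Of 12738 genes tested, 383 were higher and 66 lower after papain. After scaling, 722 of 12507 were higher and 519 lower, and 341 were higher and 61 lower on both scales. The other largest rises were in Sprr2a1, Sprr2a2 and Sprr2a3, which encode cornified envelope proteins (log2 changes 6.68, 6.71 and 6.06), Chil3 (4.24) and the lipoxygenase gene Alox12e (3.96). The Sprr2a genes are near-identical copies whose reads could be split between them, and Sprr2a1 and Sprr2a2 overlap in the annotation, so their separate levels are uncertain. The same holds for Ear2 and for the paired chitinase-like genes Chil3 and Chil4. The remaining largest falls were in Olfr1507 (-2.10), Olfr726 (-1.91), Olfr1228 (-1.73), Olfr195 (-1.64) and Kirrel2 (-1.72), an adhesion gene of olfactory axons.

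Among the gene lists fixed beforehand, the IL-13-response and goblet cell genes moved furthest, with 10 of 13 tested members higher (11 when adjusted over the list alone; camera adjusted p = 1.91e-26, and adjusted p = 0.029 with an estimated correlation). Its members included Clca1, from 0.00559 to 5.36 ± 2.65 FPKM, the gel-forming mucin Muc5ac, from 3.41 ± 1.84 to 23.9 ± 8.85 FPKM, and the lectin Itln1, from 1.34 ± 0.597 to 25.5 ± 1.96 FPKM. Alternatively activated macrophage genes rose in 4 of 6 (adjusted p = 1.59e-10; adjusted p = 0.0374 with an estimated correlation). Mast cell and basophil markers rose in 2 of 4 (adjusted p = 1.24e-06; adjusted p = 0.029 with an estimated correlation, or 0.0761 scaled). These were the mucosal mast cell proteases Mcpt1, listed at 0 in each control library and at 9.31 ± 5.61 FPKM after papain, and Mcpt2, at 7.09 ± 4.51 FPKM after papain. Of 11 listed eosinophil markers only 3 were tested, and all 3 were higher, including the ribonuclease gene Ear2 (log2 change 2.11) and Ccr1 (1.02). The list had adjusted p = 1.45e-05 by camera, and adjusted p = 0.0492 with an estimated correlation, or 0.058 scaled. Without control library 2 or papain library 3 Ccr1 was not called (adjusted p = 0.0744 and 0.125). The eosinophil granule genes Epx and Prg2 and the receptor gene Siglecf were under the filter on low values and were not tested. Their papain means were 0.00522, 0.823 and 0.212 FPKM. The call of the eosinophil list therefore rests on the 3 tested members, and whether other cells expressed these was not tested.

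Type 2 cytokines and chemokines were higher in 5 of 7 tested members, with Ccl8 from 2.35 ± 1.2 to 24.2 ± 5.29 FPKM (camera adjusted p = 1.25e-07; adjusted p = 0.0986 with an estimated correlation). Il5 and Il13 were too low to be tested, at 0.0697 and 0.00916 FPKM in controls and 0.75 and 0.6 FPKM after papain. Il4 did not pass (log2 change -0.00, adjusted p = 0.995), and Tslp was under the filter at 0.275 FPKM. The alarmin gene Il33 was at 28.5 ± 1.33 FPKM in controls and 21.2 ± 4.37 after papain, with adjusted p = 0.272 as deposited and 0.0011 in the scaled values (log2 change -0.66). Tuft cell markers rose in 5 of 8, among them the taste-type G protein gene Gnat3 (log2 change 1.23) and the prostaglandin D synthase gene Hpgds (1.55; list adjusted p = 2.97e-07, and adjusted p = 0.126 with an estimated correlation). The eicosanoid pathway was higher in 5 of 12, led by Alox15 (1.68; adjusted p = 1.25e-04, and adjusted p = 0.313 with an estimated correlation). Alox15 is also a member of the IL-13-response list, and Hpgds of both the tuft cell and eicosanoid lists.

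Neutrophil markers were higher in 5 of 9, with the siderophore-binding gene Lcn2 from 11.1 ± 0.659 to 186 ± 92 FPKM and Retnlg at a log2 change of 1.46 (adjusted p = 2.97e-07; adjusted p = 0.105 with an estimated correlation). Monocyte and macrophage markers were higher in 5 of 13, such as C1qa (1.05) and Ccr2 (1.01), and dendritic cell and MHC class II genes in 2 of 8, H2-Ab1 (1.23) and Cd74 (1.16). Camera gave these lists adjusted p = 5.01e-05 and 6.33e-04, and both had adjusted p = 0.344 with an estimated correlation. Pro-inflammatory cytokines rose in 5 of 9, including Il1b (1.74) and Ccl7 (0.81), and interferon response genes in 2 of 12, Oasl2 (0.87) and Usp18 (0.75). Their adjusted p values were 1.24e-06 and 3.57e-04, or adjusted p = 0.254 and 0.419 with an estimated correlation. B and plasma cell markers were higher in 2 of 3, Xbp1 (0.70) and the joining chain gene Jchain (3.73, adjusted p = 0.00655 as deposited and 0.0725 scaled; list adjusted p = 9.96e-04, and adjusted p = 0.174 with an estimated correlation). Leaving out the library in brackets, each alone, ended the calls of C1qa (papain 3; adjusted p = 0.0503), H2-Ab1 (papain 3; adjusted p = 0.0612), Cd74 (control 1, papain 3; adjusted p = 0.0593 to 0.0934), Il1b (papain 3; adjusted p = 0.0969), Ccl7 (control 1 and 3, papain 3; adjusted p = 0.0687 to 0.164), Oasl2 (control 1, 2 and 3, papain 1; adjusted p = 0.0615 to 0.106), Usp18 (control 1, 2 and 3, papain 3; adjusted p = 0.0819 to 0.203) and Xbp1 (control 1, 2 and 3, papain 1 and 3, exosome 2; adjusted p = 0.0594 to 0.278).

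Olfactory sensory neuron markers lay lower than other genes after papain, with a median log2 change of -0.70 (camera adjusted p = 3.16e-17; adjusted p = 0.174 with an estimated correlation). Only the channel gene Kcnmb3 passed among 16 members as deposited (log2 change -1.13), against 10 after scaling. Sustentacular cell markers had 0 higher and 0 lower of 12 as deposited, and 1 higher and 3 lower after scaling (camera adjusted p = 0.0929 and 0.0816). Epithelial junction genes rose in 3 of 13, including Cldn4 (1.29) and Cdh1 (1.01), and basal cell markers in 2 of 8, Krt14 (1.04) and Krt15 (0.90, and 0.67 with adjusted p = 0.159 scaled). Camera adjusted p values were 0.0271 and 9.27e-04, with adjusted p = 0.517 and 0.344 with an estimated correlation. Nasal gland products did not move together (adjusted p = 0.225), with 3 higher, among them Bpifb1 (2.12) and Scgb3a1 (2.49), and 2 lower. Matrix and remodelling genes had 1 of 23 higher, Timp1 (1.38; list adjusted p = 0.849). The remodelling genes Postn (adjusted p = 0.749), Col1a1 (0.827) and Tgfb1 (0.259) did not pass. Calls ended on leaving out 1 library for Kcnmb3 (control 1 and 2, papain 3; adjusted p = 0.0516 to 0.0934), Cdh1 (papain 3; adjusted p = 0.0823), Krt15 (control 2 and 3, papain 1; adjusted p = 0.0549 to 0.229) and Timp1 (papain 3; adjusted p = 0.0601). With array weights Postn (0.29), Tgfb1 (0.72) and Il33 (-0.34) passed.

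Of the remaining lists, proliferation genes (Birc5, log2 change 0.94) and immediate early and heat shock genes (Junb, 1.09) were higher by camera (adjusted p = 8.52e-04 and 0.00394), as were ciliated cell markers (0.0365). Fibroblast, endothelial and skeletal muscle genes were lower relative to other genes (adjusted p = 0.0471, 0.0471 and 3.62e-04). With an estimated correlation these 6 lists had adjusted p = 0.441, 0.511, 0.553, 0.511, 0.53 and 0.344. After scaling the ciliated, fibroblast, endothelial and skeletal muscle lists were not called (adjusted p = 0.339, 0.0823, 0.154 and 0.283). Bone and cartilage genes (Dmp1, 1.67, and Ibsp, 1.57), red blood cell genes and mitochondrially encoded genes did not differ from other genes (adjusted p = 0.465, 0.082 and 0.705). In all, 18 of 28 lists were higher and 4 lower relative to other genes. Of these, 4 held with an estimated correlation (IL-13-response, alternatively activated macrophage, mast cell and, on 3 of 11 listed members, eosinophil). After scaling 17 were higher and 1 lower, of which 3 held, the tuft cell list (adjusted p = 0.0257 with an estimated correlation) and the first 2 of these. Leaving out the library in brackets moved the genes higher to 252 (control 1), 188 (control 2), 233 (control 3), 1624 (papain 2), 150 (papain 3) and 787 (exosome 3), and lower to 34 (control 2), 141 (papain 1), 37 (papain 3) and 131 (exosome 3). After scaling it moved them to 409 (control 2), 369 (control 3) and 351 (papain 3) higher, and 280 (control 1), 210 (control 2), 207 (control 3) and 202 (papain 3) lower. Junb was not called without control library 2 or 3 or papain library 1 or 3 (adjusted p = 0.062 to 0.187). With no filter on low values Kirrel2, Ccr1, Jchain, Xbp1, H2-Ab1, Cd74, Il1b, Ccl7, Oasl2, Usp18, Timp1, Cldn4, Cdh1, Krt15, Kcnmb3, Dmp1, Ibsp and Junb were not called (adjusted p = 0.0544 to 0.207), and after rescaling to TPM (transcripts per M) Xbp1, Oasl2, Usp18 and Krt15 were not (0.235, 0.088, 0.201 and 0.0647).

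**Figure D2:**
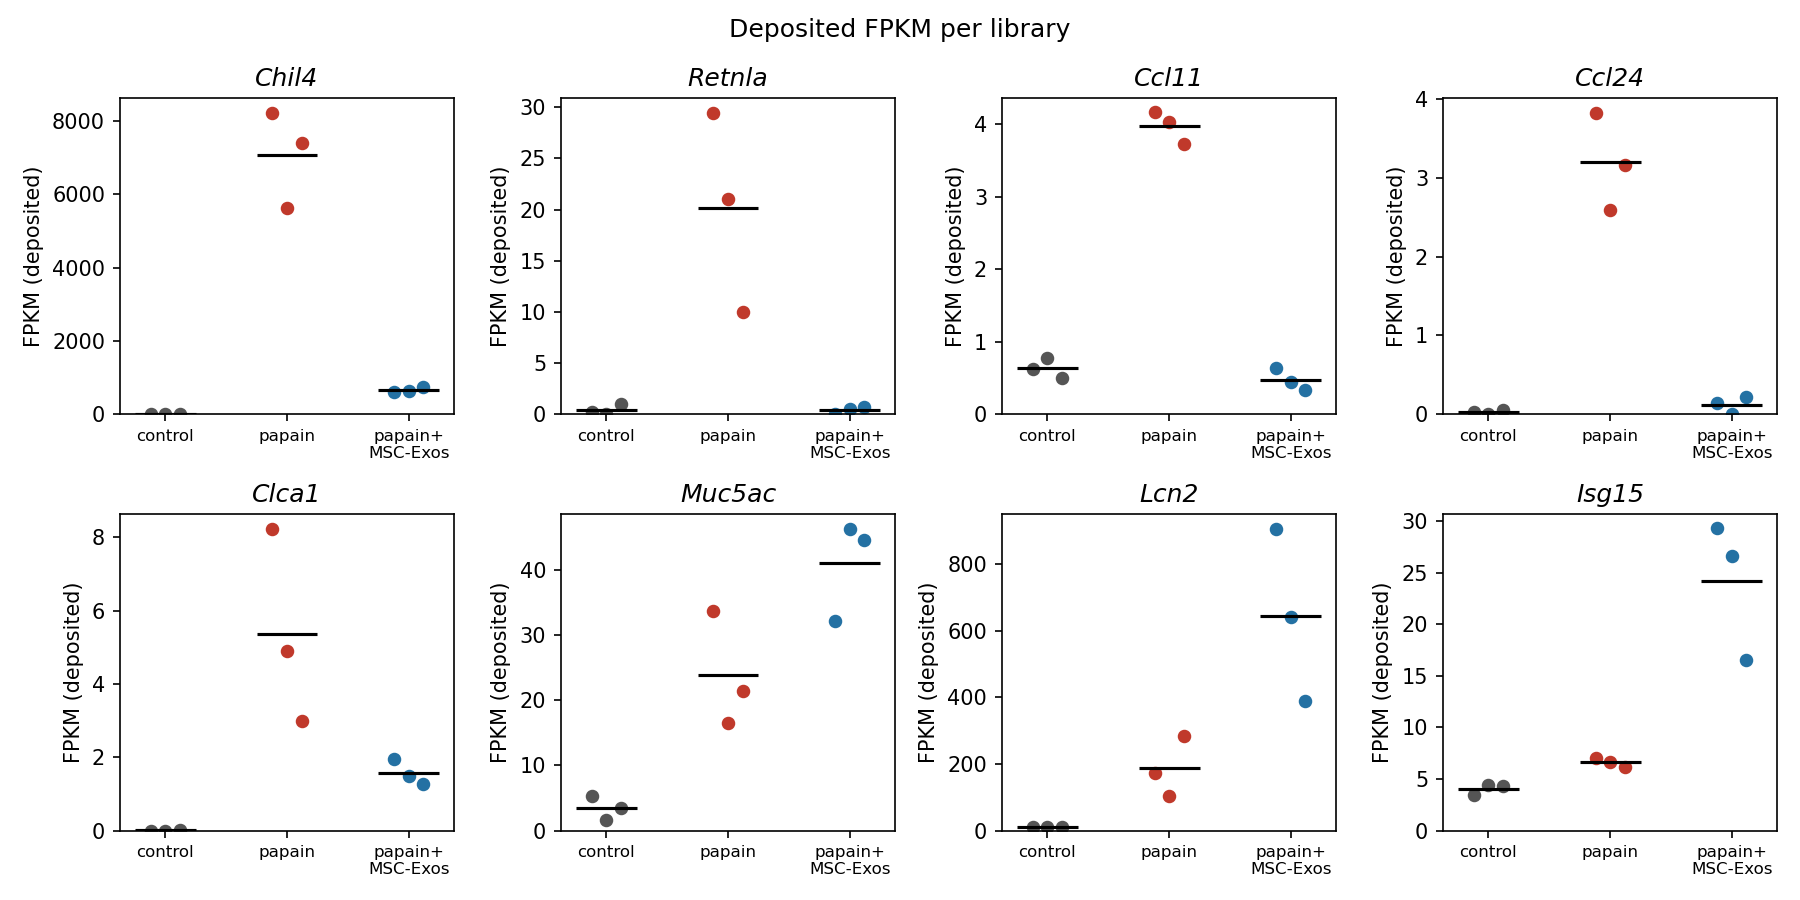
Deposited FPKM of 8 genes in each library, on linear axes from 0; points are libraries and bars are means of 3. Ccl11 was 3.97 FPKM after papain and 0.476 with exosomes, while Lcn2 was 186 and 644.

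The comparison of exosomes with papain asks what changes when the vesicles are added to the model. Several of the strongest papain genes were lower on both scales. Chil4 was 658 ± 69 FPKM with exosomes against 7075 ± 1317 after papain (log2 change -3.41 ± 0.35, adjusted p = 8.51e-06), and Retnla was 0.41 ± 0.361 against 20.1 ± 9.75 FPKM (adjusted p = 2.85e-07). Ccl11 fell to 0.476 ± 0.154 FPKM (log2 change -1.76, adjusted p = 2.44e-06) and Ccl24 to 0.122 ± 0.113 FPKM (-1.90, adjusted p = 5.52e-07). In contrast, Lcn2 rose to 644 ± 259 FPKM (log2 change 1.82 as deposited and 1.11 scaled) and the ubiquitin-like interferon gene Isg15 from 6.63 ± 0.448 to 24.2 ± 6.79 FPKM (1.68 and 1.01).

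As deposited, 8022 genes were higher and 93 lower with exosomes, and after scaling 1672 were higher and 2022 lower, so the split of directions rests on the scale. Leaving out exosome library 1 gave 4819 higher as deposited, and after scaling leaving out the library in brackets moved the genes higher to 1107 (papain 2), 964 (papain 3), 726 (exosome 1) and 787 (exosome 2) and lower to 1266 (papain 3), 1031 (exosome 1) and 1111 (exosome 2). On both scales 1665 were higher and 87 lower, and 12 were higher as deposited but lower scaled. The other largest falls were in Sprr2a3 (-3.63), Sprr2a1 (-3.34), Mcpt1 (-2.71) and Mcpt2 (-2.23). The largest rises were in Kirrel2 (log2 change 2.92, scaled 2.24), the acute-phase gene Saa3 (2.45, scaled 1.78), the olfactory gene Gfy (2.38, scaled 1.67), Chga (2.27, scaled 1.57) and Rasgrp4 (2.25, scaled 1.70). Sbpl passed as deposited only (2.29; scaled 1.87, adjusted p = 0.107).

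Type 2 cytokines and chemokines were lower in 5 of 7 tested members and higher in 2, and after scaling lower in 5 and higher in 0 (camera adjusted p = 6.63e-20 and 5.34e-04; adjusted p = 0.0109 and 0.0738 with an estimated correlation). Alternatively activated macrophage genes were lower in 4 of 6 on either scale, Chil3 among them (from 35.9 ± 16.2 to 7.62 ± 0.797 FPKM), with adjusted p = 1.26e-18 and adjusted p = 0.00911 with an estimated correlation. After scaling these were 1.03e-04 and, with an estimated correlation, adjusted p = 0.0738. Mast cell and basophil markers fell in 2 of 4 and rose in 1, which did not pass after scaling (adjusted p = 1.50e-08; scaled 0.0856), and eosinophil markers had 1 lower, Ear2 (-1.77), and 1 higher, Cd300lf (0.53, not past the threshold scaled, adjusted p = 0.716), and 2 lower and 0 higher scaled (list adjusted p = 1.05e-05, scaled 0.144). Il5 and Il13, not tested, were at 0.104 and 0.0724 FPKM with exosomes. Prg2 and Siglecf, not tested, were at 0.465 and 0.566 FPKM. Cd300lf was at 0.29 without papain library 2, 0.35 without exosome library 1 and 0.51 without exosome library 2, and not called (adjusted p = 0.241, 0.2 and 0.0761).

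The IL-13-response and goblet cell list split. As deposited 3 of 13 were lower and 3 higher, and after scaling 8 were lower and 0 higher (camera adjusted p = 6.38e-13 and 3.41e-04; adjusted p = 0.0408 and 0.0738 with an estimated correlation). Clca1 fell from 5.36 ± 2.65 to 1.57 ± 0.344 FPKM (log2 change -1.23, scaled -1.68). Muc5ac was at 41 ± 7.68 FPKM with exosomes, higher as deposited (0.80, adjusted p = 0.0204) and not past the threshold after scaling (0.11, adjusted p = 0.841). Without papain library 2 or 3 or exosome library 2 Muc5ac was not called as deposited either (0.57, 0.75 and 0.70; adjusted p = 0.108, 0.0507 and 0.0505).

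Interferon response genes were higher in 11 of 12 tested members, and in 8 of 11 after scaling, with Oasl2 at 1.74 (scaled 1.06). Olfactory sensory neuron markers were higher in 16 of 16, and in 13 after scaling, with Ano2 at 2.17 (scaled 1.52) and Kcnmb3 at 1.95 (scaled 1.40). These were the only lists higher by camera on either scale (adjusted p = 3.35e-06 and 2.12e-06 as deposited, 7.63e-06 and 5.89e-06 scaled). With an estimated correlation they had adjusted p = 0.317 and 0.379 as deposited and 0.478 each scaled. Sustentacular markers were not called (adjusted p = 0.299), although Sec14l3 (1.66, scaled 0.95) and Cyp2f2 (1.12, scaled 0.40) rose. Junction genes Tjp3 (1.39, scaled 0.72) and Cgn (1.09, scaled 0.44) and the ciliary gene Ccdc40 (1.31, scaled 0.66) rose, while their lists were not called (adjusted p = 0.854 and 0.083).

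The basal keratin Krt14 fell from 22.1 ± 1.14 to 14.4 ± 2.3 FPKM (log2 change -0.60, scaled -1.26), and the prostaglandin synthase gene Ptgs2 from 2.38 ± 1.8 to 0.755 ± 0.571 FPKM (-0.85), which was under the filter after scaling. The lists of basal cell markers (camera adjusted p = 2.23e-04), pro-inflammatory cytokines (1.86e-11), proliferation genes (2.17e-10), immediate early and heat shock genes (2.65e-07) and mitochondrially encoded genes (1.05e-05) were lower relative to other genes as deposited. So were bone and cartilage (2.12e-06), matrix (8.70e-06), skeletal muscle (2.61e-04), B and plasma cell (3.64e-05) and eicosanoid (0.0412) genes and nasal gland products (3.50e-09). Such a call can be made while members rise: the matrix list had 6 members higher and 0 lower, and the eicosanoid list 6 and 1. Only the nasal gland products, of the 11 lists, had more members lower (3) than higher (2). Of these 11 lists only the nasal gland products held with an estimated correlation (adjusted p = 0.00911), the others lying at adjusted p = 0.103 to 0.568 with an estimated correlation. After scaling the nasal gland (adjusted p = 0.05004, and adjusted p = 0.478 with an estimated correlation), pro-inflammatory (0.0604), skeletal muscle (0.766), B and plasma cell (0.124) and eicosanoid (0.314) lists were not called. The other 6 were, with adjusted p = 0.478 to 0.532 with an estimated correlation. Neutrophil (adjusted p = 0.161), monocyte and macrophage (0.36), dendritic cell and MHC class II (0.288), fibroblast (0.147), tuft (0.106), endothelial (0.106) and red blood cell (0.111) lists were not called. Ptgs2 was at -1.28 without papain library 2 and at -0.59 without exosome library 3, where it was not called (adjusted p = 0.0636), and Krt14 was at -0.24 after rescaling to TPM (adjusted p = 0.476).

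Of the named genes past the threshold on at least 1 scale, 6 turned direction with the scale. Il33 had a log2 change of 0.66 as deposited and -0.03 scaled, Tgfb1 0.55 and -0.03, and Postn 0.20 and -0.50, the last with adjusted p = 0.472 and 0.0261. The eicosanoid genes Lta4h (0.64 and -0.0166) and Alox5ap (0.43 and -0.16) and the heat shock gene Dnajb1 (0.57 and -0.0524) passed as deposited and not scaled. Il4 was higher as deposited (0.70, adjusted p = 0.0076) and not past the threshold scaled (adjusted p = 0.144), as were Cd74 (scaled 0.61, adjusted p = 0.0648) and Lyz2 (0.20, 0.505). Col1a1 did not pass on either scale (adjusted p = 0.287 and 0.735), but passed after rescaling to TPM (0.87), with array weights (1.13) and without papain library 1 (0.83) or exosome library 3 (1.10; adjusted p = 0.00905, 3.53e-13, 0.0415 and 0.0055). As deposited Postn passed without exosome library 3 (0.51, adjusted p = 0.0448) and with array weights (0.17), and Tgfb1 did not pass without papain library 2 or exosome library 1 or 2 (0.38, 0.34 and 0.50; adjusted p = 0.16, 0.21 and 0.104). Without control library 2 Tgfb1 did not pass either, with adjusted p = 0.0506. Leaving out 1 library also ended the deposited calls of Lta4h (exosome 1; adjusted p = 0.0582), Dnajb1 (papain 2, exosome 1 and 2; adjusted p = 0.0628 to 0.0893) and Alox5ap (control 1, 2 and 3, papain 1, 2 and 3, exosome 1 and 2; adjusted p = 0.0696 to 0.172). With no filter on low values Cd300lf, Alox5ap, Sbpl, Ptgs2, Muc5ac and Tgfb1 were not called (adjusted p = 0.0523 to 0.102). In all, 2 of 28 lists were higher and 16 lower relative to other genes as deposited, against 2 and 9 after scaling. Of these calls 6 and 0 held with an estimated correlation.

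Of the 449 genes that passed in the papain comparison, 43.4% changed in the opposite direction with exosomes as deposited, and 79.6% of the 1241 after scaling. As deposited the share was 77.9% after quantile normalization, 17.1% with array weights and 27.4% without exosome library 3. Both comparisons use the same papain libraries. With genes selected in the other papain libraries and measured against papain library 1, 2 or 3, the share was 60.7%, 8% and 57.2% as deposited and 70.7%, 66.7% and 83% scaled. Genes raised by papain and called lower with exosomes, such as Chil4, Retnla, Ccl11 and Ccl24, numbered 48 as deposited and 313 scaled, and genes lowered by papain and called higher, such as Kirrel2 and Kcnmb3, 56 and 258. Were the calls of the comparisons independent, the first count would be 2.8 as deposited and 117 scaled. The second would be 41.6 and 69.4, since most genes were higher with exosomes as deposited. In 100 simulations that share the papain libraries and hold no exosome change, the shares were 84% to 100% as deposited and 54.3% to 94.9% scaled, the first counts 4 to 368 and 0 to 7, and the second counts 0 to 23 and 0 to 1.

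**Figure D3:**
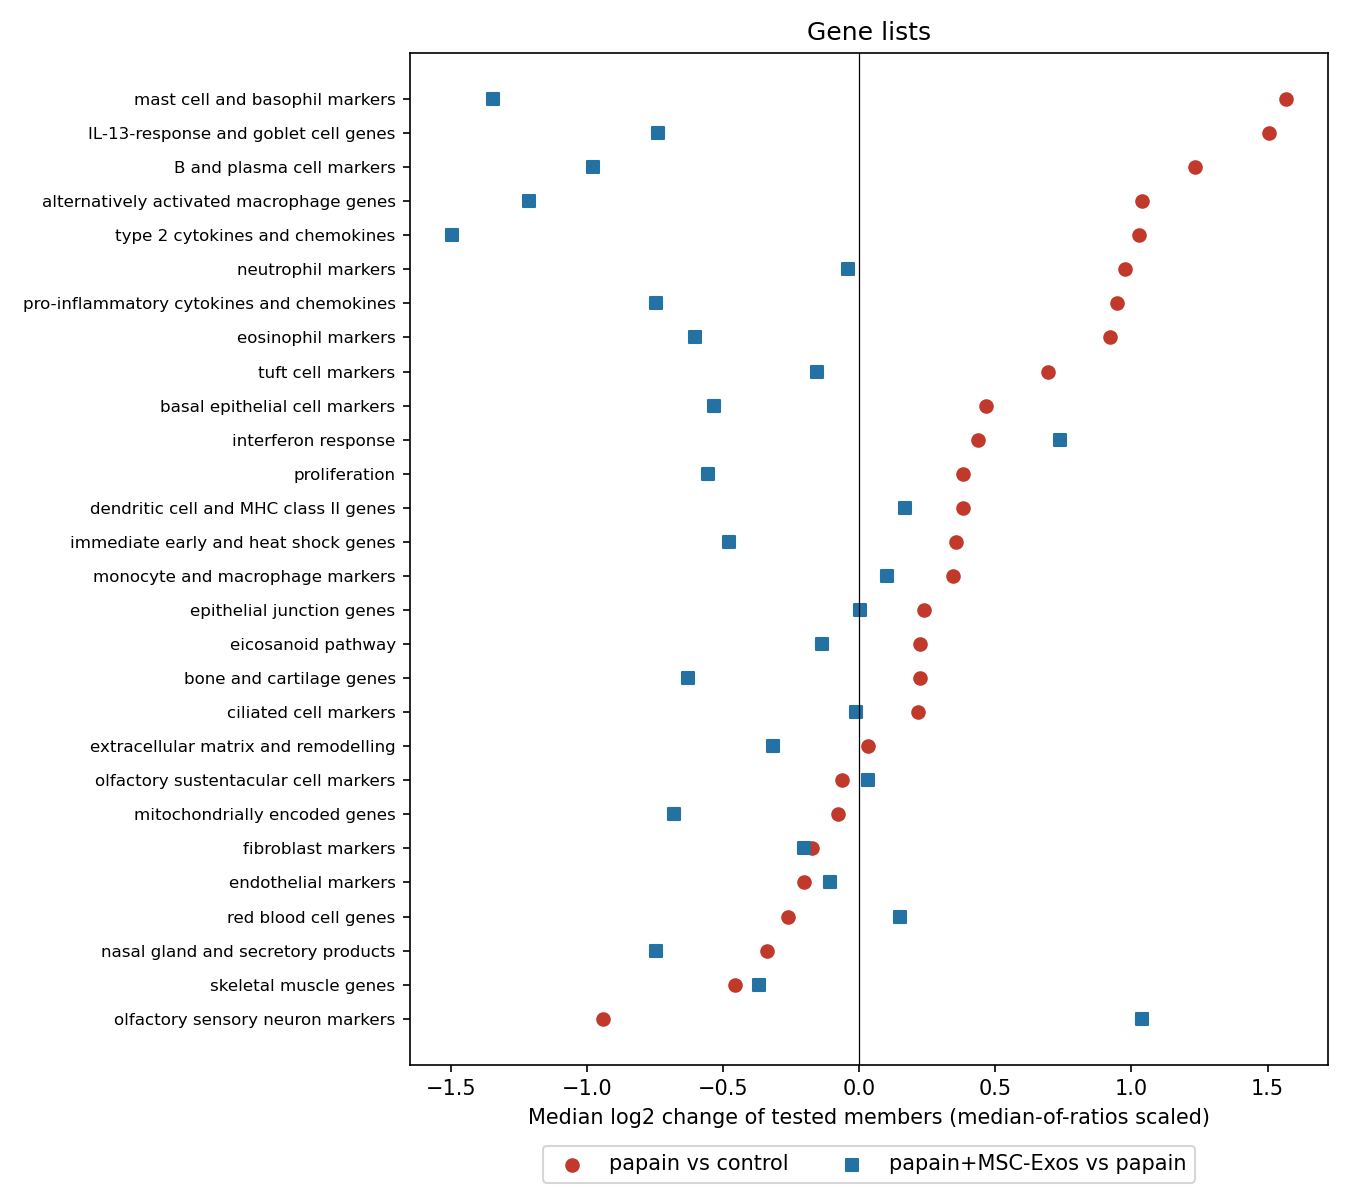
Median log2 change of the tested members of 28 gene lists after median-of-ratios scaling, for papain against control (circles) and exosomes against papain (squares). Olfactory sensory neuron markers were at -0.94 and 1.04, and type 2 cytokines and chemokines at 1.03 and -1.50.

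The comparison of exosomes with control asks what differed from control mucosa when papain and exosomes were both given. Chil4 was 6.68 ± 0.35 above control on the log2 scale (adjusted p = 2.03e-10), and Lcn2 5.66 ± 0.30 above it (adjusted p = 2.03e-10). The neutrophil surface gene Cd177 rose from 3.94 ± 2.3 to 171 ± 63.5 FPKM, Saa3 from 0.0229 ± 0.0397 to 23.5 ± 6.45 FPKM, and Muc5ac from 3.41 ± 1.84 to 41 ± 7.68 FPKM (scaled log2 change 2.48). Ccl24 (adjusted p = 0.467) and Retnla (0.938) did not differ detectably from control on either scale, and Ccl11 had adjusted p = 0.391 as deposited and was lower than control scaled (-0.47, adjusted p = 0.0287). The lipocalin gene Obp2b (chromosome 2, 25737009 to 25740097) fell from 12616 ± 1793 to 3451 ± 1063 FPKM (log2 change -1.90 ± 0.27, adjusted p = 4.58e-05).

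As deposited, 10736 genes were higher and 67 lower than in controls, and after scaling 1540 were higher and 1954 lower. Leaving out the library in brackets moved the scaled genes higher to 951 (control 1), 789 (control 3), 605 (exosome 1) and 845 (exosome 2), and lower to 1116 (control 1), 1085 (control 3), 881 (exosome 1) and 1133 (exosome 2). On both scales 1540 were higher and 65 lower, and 757 were higher as deposited but lower scaled. The other largest rises were in Sprr2a2 (4.97, scaled 4.28) and Itln1 (3.49, scaled 2.72). The other largest falls were in secreted products, namely Wfdc12 (-1.95), Scgb1b27 (-1.81), the exocrine peptide gene Esp8 (-1.65), Lcn11 (-1.59) and Mup4 (-1.53). Mup4 and Obp2b belong to families of close paralogs, so their levels are uncertain. After quantile normalization Lcn11 (-0.75) and Mup4 (-0.44) were not called (adjusted p = 0.0992 and 0.0882).

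Interferon response genes were higher in 12 of 12 tested members and in 11 of 11 scaled, led by Oasl2 (log2 change 2.61, scaled 1.74) and Isg15 (2.28, scaled 1.42). Monocyte and macrophage markers were higher in 12 of 13 and 10 of 12 scaled, such as C1qa (scaled 0.86) and Lyz2 (scaled 0.81). Dendritic cell and MHC class II genes were higher in 8 of 8 and 5 of 9 scaled, with Cd74 (1.54) and H2-Ab1 (1.55) as examples. The IL-13-response and goblet cell list (11 of 13, scaled 8 with 1 lower), neutrophil markers (8 of 9, scaled 3 of 8; Csf3r scaled 1.08) and tuft cell markers (8 of 8, scaled 6 of 7; Gnat3 scaled 0.88) were also higher. Camera adjusted p values for these 6 lists as deposited were 6.76e-09, 6.62e-04, 0.00395, 2.65e-05, 0.0152 and 0.00911, and all were called after scaling too. With an estimated correlation they lay at adjusted p = 0.503 to 0.51, and at 0.16 to 0.508 scaled. Ciliated cell markers were called as deposited (adjusted p = 0.00247; adjusted p = 0.567 with an estimated correlation) and not scaled (0.134), and junction genes, Tjp3 and Cldn3 among them, were called scaled (0.0136; adjusted p = 0.282 with an estimated correlation) and not as deposited (0.151).

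Nasal gland products had 6 of 13 lower and 5 higher, the latter including the antimicrobial genes Bpifb1 (log2 change 3.22, scaled 2.33) and Ltf (2.08, scaled 1.13). This list was lower by camera (adjusted p = 1.48e-14), and was the only list of this comparison to hold with an estimated correlation (adjusted p = 0.00509), though not called after scaling (0.241). Type 2 cytokines (0.00188), matrix (9.50e-05), fibroblast (6.62e-04), endothelial (0.00111), skeletal muscle (1.44e-12), bone and cartilage (1.42e-04), proliferation (0.00637), immediate early and heat shock (0.0155) and mitochondrially encoded (7.38e-06) genes were lower relative to other genes (camera adjusted p as deposited; adjusted p = 0.351 to 0.711 with an estimated correlation). As deposited none of these lists had more members lower than higher. Members higher and lower were 11 and 0 for matrix, 5 and 0 for fibroblast, 4 and 0 for endothelial, and 6 and 0 for immediate early and heat shock genes. After scaling the matrix, fibroblast and mitochondrially encoded lists were called (0.0417, 0.0241 and 5.56e-04; adjusted p = 0.781, 0.282 and 0.508 with an estimated correlation). The type 2 (0.492), endothelial (0.0563), skeletal muscle (0.288), bone and cartilage (0.362), proliferation (0.288) and immediate early and heat shock (0.923) lists were not. Lists not called were eosinophil (0.978), alternatively activated macrophage (0.364), mast cell (0.72), B and plasma cell (0.692), pro-inflammatory (0.121), eicosanoid (0.282), basal cell (0.669), olfactory sensory neuron (0.508), sustentacular (0.978) and red blood cell (0.72) genes. In all, 7 of 28 lists were higher and 10 lower relative to other genes as deposited, and 7 and 3 after scaling. Il33 had a log2 change of 0.23 as deposited (adjusted p = 0.264) and -0.70 scaled (9.90e-04), and Postn 0.37 (0.171) and -0.57 (0.0176). Socs2 was 0.75 as deposited and -0.17 scaled (adjusted p = 0.00179 and 0.277). Tgfb1 was higher as deposited (1.05) and not past the threshold scaled (adjusted p = 0.0665), and Col1a1 did not pass on either scale (0.49 and 0.285). As deposited without exosome library 3, Postn (0.67, adjusted p = 0.00817) and Col1a1 (0.91, 0.0141) passed. After rescaling to TPM Postn (0.83), Col1a1 (0.77) and Il33 (0.70) were higher than control (adjusted p = 0.0109, 0.0142 and 0.0339), and with array weights they passed too (0.46, 0.74 and 0.23).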

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

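The combinations of median-of-ratios scaling with another setting were chosen after seeing the data; the other settings were set before. Of 3386 log2 changes of 184 named results under these settings, 3137 kept their side of the threshold, 212 no longer passed and 22 newly passed. The other 15 turned direction while past the threshold under the main or the other setting. A turn between values that passed neither time counts among the 3137. Under median-of-ratios scaling, log2 changes for exosomes against papain turned to Lta4h -0.0166, Alox5ap -0.16, Dnajb1 -0.0524, Il33 -0.0346, Postn -0.50 and Tgfb1 -0.0291. Under quantile normalization, log2 changes for exosomes against papain turned to Alox5ap -0.18, Dnajb1 -0.0483 and Tgfb1 -0.0585. Under median-of-ratios scaling, log2 changes for exosomes against control turned to Socs2 -0.17, Il33 -0.70 and Postn -0.57. Under quantile normalization, log2 changes for exosomes against control turned to Socs2 -0.044, Vwf -0.0178 and Il33 -0.56. The cause was not tested for these.

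The counts of calls moved with most settings. Pseudocount 0.1 gave lists 2 lower (papain against control). No filter on low values gave genes 166 higher and 41 lower (papain against control), lists 2 lower (papain against control) and 62.3% moving back. FPKM of at least 5 in 3 libraries gave genes 22 lower (papain against control), lists 1 lower (papain against control), genes 4467 higher and 56 lower (exosomes against papain), lists 8 lower (exosomes against papain), genes 6046 higher (exosomes against control), lists 6 lower (exosomes against control) and 30.6% moving back. Median-of-ratios scaling gave genes 722 higher and 519 lower (papain against control), lists 1 lower (papain against control), genes 1672 higher and 2022 lower (exosomes against papain), lists 9 lower (exosomes against papain), genes 1540 higher and 1954 lower (exosomes against control), lists 3 lower (exosomes against control) and 79.6% moving back. Quantile normalization gave genes 655 higher and 511 lower (papain against control), lists 2 lower (papain against control), genes 1744 higher and 1763 lower (exosomes against papain), lists 7 lower (exosomes against papain), genes 1557 higher and 1786 lower (exosomes against control), lists 2 lower (exosomes against control) and 77.9% moving back. Rescaled to TPM gave lists 2 lower (papain against control), lists 4 higher (exosomes against papain), genes 50 lower (exosomes against papain) and genes 31 lower (exosomes against control). Only the 2 groups compared gave genes 718 higher and 128 lower (papain against control). Replicate block gave lists 2 lower (papain against control). Array weights gave genes 8853 higher and 890 lower (papain against control), genes 851 lower (exosomes against papain), lists 1 higher (exosomes against control), genes 200 lower (exosomes against control) and 17.1% moving back. Adjusted p under 0.05 and log2 change of at least 1 gave genes 187 higher and 33 lower (papain against control), genes 1115 higher and 37 lower (exosomes against papain) and genes 2855 higher and 24 lower (exosomes against control). Unadjusted p under 0.05 and log2 change of at least 1 gave genes 192 higher and 40 lower (papain against control), genes 1116 higher and 37 lower (exosomes against papain) and genes 2855 higher and 24 lower (exosomes against control). Camera with an estimated correlation gave lists 4 higher and 0 lower (papain against control), lists 0 higher and 6 lower (exosomes against papain) and lists 0 higher and 1 lower (exosomes against control). Fry gave lists 10 higher and 0 lower (papain against control), lists 6 higher and 3 lower (exosomes against papain) and lists 15 higher and 0 lower (exosomes against control). Selecting genes in all but 1 papain library and measuring against library 1, 2 or 3 in turn gave 60.7%, 8% and 57.2% moving back. Leaving out each library gave 150 (without papain library 3) to 1624 (without papain library 2) for genes higher, papain against control, 34 (without control library 2) to 141 (without papain library 1) for genes lower, papain against control and 1 (without papain library 3) to 6 (without papain library 2) for lists lower, papain against control. It gave 4819 (without exosome library 1) to 9529 (without exosome library 3) for genes higher, exosomes against papain and 27.4% (without exosome library 3) to 56.7% (without papain library 1) for share moving back. Fewer genes are tested under a filter at 5 FPKM and fewer libraries enter when 1 is left out; otherwise the cause was not tested. A leave-out that leaves 2 libraries in a group pools the spread over all groups.

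The shared numbers gave no sign of pairing: deviations of same-numbered libraries correlated at -0.31 to 0.14, with 2 of 9 above 0.1. Differently numbered libraries of different groups ran from -0.41 to 0.40, with 5 of 18 above 0.1. With 3 libraries per group this check cannot exclude pairing. With a replicate block the genes higher and lower were 415 and 82 (papain against control), 7823 and 100 (exosomes against papain) and 10614 and 68 (exosomes against control), and 44.3% moved back.

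After median-of-ratios scaling, where 722 and 519, 1672 and 2022, and 1540 and 1954 genes were higher and lower, the further settings moved these. Only the 2 groups compared gave lists 2 lower (papain against control). Array weights gave genes 1273 higher and 1126 lower (papain against control), lists 3 lower (papain against control), genes 2568 higher (exosomes against papain) and genes 2445 higher (exosomes against control). Camera with an estimated correlation gave lists 3 higher and 0 lower (papain against control), lists 0 higher and 0 lower (exosomes against papain) and lists 0 higher and 0 lower (exosomes against control). Fry gave lists 2 lower (papain against control) and lists 14 lower (exosomes against papain). Selecting genes in all but 1 papain library and measuring against library 1, 2 or 3 in turn gave 70.7%, 66.7% and 83% moving back. Leaving out each library gave 351 (without papain library 3) to 769 (without exosome library 3) for genes higher, papain against control, 202 (without papain library 3) to 616 (without papain library 1) for genes lower, papain against control and 1 (without control library 3) to 3 (without papain library 2) for lists lower, papain against control. It gave 726 (without exosome library 1) to 1677 (without papain library 1) for genes higher, exosomes against papain, 1031 (without exosome library 1) to 2212 (without exosome library 3) for genes lower, exosomes against papain and 605 (without exosome library 1) to 1690 (without papain library 1) for genes higher, exosomes against control. It gave 881 (without exosome library 1) to 2083 (without exosome library 3) for genes lower, exosomes against control and 77.8% (without exosome library 3) to 85.8% (without papain library 1) for share moving back. The cause was not tested. At the estimated depths Il5 and Il13 averaged under 1 FPKM in each group, and whether depth limits them was not tested.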

Other observations

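The tests of fragment share, depth, scaling, papain libraries left out of the selection after scaling, goblet cell genes and olfactory epithelium were chosen after the results were seen; the comparison with simulated libraries and the splits were set before.

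The table holds 1135 genes named as odorant receptors, a group chosen after its leading members were seen. Of the 179 tested, 43 were lower and 0 higher after papain (91 and 0 scaled, median log2 change -0.59). With exosomes against papain, 103 were higher and 0 lower (46 and 1 scaled). Of all 12738 genes tested, 8022 were higher and 93 lower there, so the deposited 103 of 179 is not above the general share. After scaling 1672 of all 12507 were higher and 2022 lower, a smaller share higher than among the receptor genes. Against control the direction of the receptor genes turned with the scale, 64 higher and 4 lower as deposited but 1 higher and 56 lower scaled. Over all genes the counts were 10736 higher and 67 lower as deposited, and 1540 and 1954 scaled. The olfactory neuron list did not follow the receptor genes against control, with a scaled median of -0.00.

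On deposited FPKM most genes were higher with exosomes than after papain, with a median log2 change of 0.56. Setting the length-weighted FPKM outside the 15 highest genes to a common sum left a median of 0.15, a removal of 73.9%. For papain against control the same step turned the median from 0.19 to -0.06, and for exosomes against control it went from 0.76 to 0.11. Dividing by the sum of the other genes shrinks any shift that they share, whatever its cause. The step therefore cannot show that the loss of gland transcripts such as Obp1a and Mup4 accounts for the shift. Estimated depth differed by -3.04 ± 2.64 M fragments (M, mega, exosome minus papain, SE) with overlapping ranges, which gives no sign of a depth effect but rests on a rough estimate bounded by a hand-set window. Whether the gland transcripts fell in the tissue or less gland was sampled stays open, and the exosome treatment remains an untested explanation.

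Genes changed by papain moved back with exosomes in 79.6% of cases after scaling, with 313 raised genes called lower and 258 lowered genes called higher, beside up to 94.9%, 7 and 1 in 100 simulations with no exosome change (as deposited 43.4%, 48 and 56 beside 100%, 368 and 23). The simulated shares move back by construction, and exosome changes unrelated to those of papain could also raise the counts. Independent calls alone would give 117 and 69.4 scaled, and 2.8 and 41.6 as deposited, fewer than the counts seen. Unrelated exosome changes and shared papain libraries acting together were not simulated. Neither the shares nor the counts therefore decide what the shared papain libraries contribute. Against papain libraries left out of the selection 70.7%, 66.7% and 83% moved back, while among papain libraries alone, in 1 order or the mirrored 1, the share ran from 20.6% to 79.4%, so this stays open too. Under each of 4 scalings at least 10.8% of papain-raised genes were called lower and of papain-lowered genes higher, while 1 factor per library moves all genes the same way, which argues against scale as the whole cause. Among 10 papain-raised members of the IL-13-response and goblet cell list, 11 of 45 pairs differed in their scaled change after Bonferroni adjustment. The changes ran from Chil4 at -4.13 to Muc5b at 0.12, so an equal fractional loss of every member would not give the pattern. A loss of such cells need not lower all members equally. Other cells may express some of them, and the log2(FPKM + 1) scale compresses changes of low genes. Loss of these cells, differences among the shared papain libraries, a change in the state of these cells and an exosome effect therefore stay open.

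Olfactory sensory neuron markers changed by -0.89 ± 0.25 (SE, n = 3 per group) after papain and 0.91 ± 0.30 with exosomes in scaled mean log2 values, and sustentacular markers by -0.17 ± 0.11 and 0.07 ± 0.10. Uneven capture of olfactory epithelium would move both alike if that epithelium alone expressed both lists, which was not checked. If other nasal cells also express sustentacular list members, that list would move less. The sustentacular change minus 50% of the neuron change, in the direction of the neurons, was -0.277 ± 0.0384 and -0.382 ± 0.0746 (SE), and the median member moved by -0.0642 and 0.0325 (SD over members 0.37 and 0.40). These values argue against uneven capture as the whole cause only if the sustentacular list is particular to olfactory epithelium. Members did move, 3 lower and 1 higher of 12 after papain and 3 higher and 0 lower with exosomes, Sec14l3 and Cyp2f2 with the neurons both times, so a part from capture stays open. Loss and return of neurons, or of their transcripts, is a hypothesis that these values leave open, and papain library 2 held the lowest neuron mean (3.83 against 4.70 and 4.27).

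Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. In each comparison 1 split, the real 1, called as many genes: 449 for papain against control, where the highest other split called 2, 8115 for exosomes against papain, where it called 1, and 10803 for exosomes against control, where it called 4. Each other split mixes libraries of both groups on each side. Any real difference then enters the spread, so low counts there follow largely from the design.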
